A study of Mus musculus with 13 samples.

How the data were processed

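Gene expression was measured in 13 samples of sorted mouse hematopoietic stem and progenitor cells with Illumina bead arrays. RNA was isolated with a column kit and amplified to biotinylated cRNA, per the labels' protocols. The deposited table of unnormalized values gives, per the file headers, a probe intensity on a linear scale and a detection p-value for each probe and array. The detection p-value tells how a probe's signal compares with that of negative control probes on the same array, and the authors' scanner software, its version and its handling of background are not given in the sources used here. The intensity columns had no common scale, with medians between 51.7 and 52.9 on the 3 LTHSC arrays and between 148.31 and 191.03 on the other 10. A second deposited table holds the authors' processed intensity values of the same arrays, on a linear scale and without centring. Its columns kept the rank order of the unnormalized signals (rank correlation 1 after rounding). Their medians were 52.2 for each of the 3 LTHSC arrays, 175.85 for the +/+ STHSC, MPP and CMP, 175.86 for the A/- STHSC, 175.90 for the A/- MPP, 175.80 for the A/- CMP, 175.83 and 175.77 for the +/+ and A/- GMP, and 175.81 and 175.66 for the +/+ and A/- MEP. At equal rank the log2 values differed by at most 0.00417 between the 3 LTHSC arrays and by at most 0.0167 between the other 10. The authors had therefore brought the LTHSC arrays and the other arrays each to a common distribution, in 2 separate sets; their method is not given in the sources used here. These processed values served as an alternative.

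The unnormalized values covered 45281 probes, and 326 empty lines at the end of the table were left out. They were processed with limma 3.58.1 in R 4.3.3. The neqc function took the background from the detection p-values, added an offset of 16, normalized all 13 arrays by quantiles and took log2. Probes were named from the platform annotation, in which 34885 had 1 gene symbol, 18 had several and were left unnamed, and 10378 were not listed and stayed unnamed. Of the listed probes 34807 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez number, and 0 symbols changed. That table served only for names and for which genes neighbour each other. For each gene the probe with the highest mean over the 13 arrays was kept, giving 29453 features. A feature was tested if its detection p was under 0.01 on at least 2 arrays, which left 12807 features, 10034 with and 2773 without a gene symbol. Where a probe was detected on no array of 1 group, its fold is given as a bound. Normalization to equal distributions removes any difference in total RNA, so all changes are relative, and the offset shrinks the changes of dim probes.

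Groups were taken from the labels. The A/- and +/+ arrays were compared by limma's lmFit and eBayes with a mean-variance trend, with population as a fixed block over 6 pairs, and in 1 fit with an effect each for LSK cells and committed progenitors, whose difference was tested as a contrast. Population contrasts came from the same 12 arrays with genotype as a covariate. The -/- array was left out of these fits, having no partner outside LTHSC. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons of 1 array with 1 array had no test, and features at least 2-fold apart, with the brighter array at a detection p under 0.01, were counted. The chance covariance of 2 comparisons that share a control array was taken from 100 simulations. Each drew independent noise with every feature's spread from the fit over 12 arrays.

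The designs, alternatives, gene lists and naming rule were fixed before the data were examined. The text names the 12 highest and 12 lowest log2 changes (8 each way between populations) among called genes with a symbol that went the same way in every pair compared. Where fewer than 10 passed, those that passed and the 10 genes with the smallest p that went 1 way in all pairs are given, and in comparisons of single arrays some of the 10 largest differences each way. Cbl, the sort markers and members of fixed lists may also be named. The 24 lists were sort markers, stem cell identity, lymphoid priming, granulocyte-monocyte progenitor, megakaryocyte-erythroid, mature neutrophil, B, T and NK cell, mast cell with basophil and eosinophil, macrophage and dendritic cell, stroma and endothelium, cell cycle, Myc and ribosome biogenesis, STAT5 targets, RAS-ERK feedback and targets, immediate early, heat shock, FOXO targets, interferon response, p53 targets, Cbl family with receptors and adaptors, HoxA and Meis, sex-linked, cytoplasmic ribosomal proteins, and respiratory chain genes. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 24 lists, and by an exact two-sided sign-flip test of the pair means. For single pairs a list's median was placed among 10000 random lists of its size matched on mean signal.

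The scripts were tested on simulated data with 50 changed features of each size among 12807. For the comparison over 6 populations 90% of those changed by 1 on the log2 scale and 98% of those changed by 2 were recovered, with 6 false calls. For LSK cells the shares were 62% and 94% (9 false calls), for committed progenitors 54% and 98% (4), and for MPP against STHSC 46% and 98% (5). Camera and fry each recovered 2 of 2 shifted lists and called 1 other. These lists held random genes with independent noise. Lists of genes that vary together were not simulated, so the calls on such lists were not checked by this. The alternatives were no background correction, an offset of 50, scaling to the 75th percentile, cyclic loess, the authors' processed values, no filter, detection on at least 6 arrays, all probes, eBayes without trend, robust eBayes, array weights, no population block, the -/- array counted as mutant, and leaving out populations. Figures were drawn with matplotlib 3.10.9.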

Results

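RNA from sorted mouse hematopoietic stem and progenitor cells was profiled on 13 Illumina mouse bead arrays. The cells came from mice of C57BL/6 background, either controls, written +/+, or carriers of mutant alleles of c-Cbl, the gene of an E3 ubiquitin ligase that marks activated receptor tyrosine kinases for degradation. The A/- genotype carried 1 allele called A over a null allele, and the -/- genotype had no intact allele. The labels do not spell out what A is. The 6 populations were long-term stem cells (LTHSC), short-term stem cells (STHSC), multipotent progenitors (MPP), common myeloid progenitors (CMP), granulocyte-macrophage progenitors (GMP) and megakaryocyte-erythroid progenitors (MEP). Each population had 1 array of +/+ and 1 array of A/- cells, and LTHSC also had 1 array of -/- cells. The first 3 populations carry Sca1 and are called LSK cells here, and the other 3 are called committed progenitors. Each array held 45281 probes, of which between 30.4% (MEP +/+) and 38.0% (LTHSC -/-) were detected. The mean probe signal lay between 248.95 and 260.23 on the 3 LTHSC arrays and between 744.09 and 1149.6 on the other 10. In 6 of 6 populations the A/- array was dimmer than its +/+ partner before normalization, with a ratio between 0.654 (GMP) and 0.957 (LTHSC). The number of arrays limits the precision. With 1 array per genotype and population, the p-values measure only how far the genotype difference varied between these populations. In contrasts between populations they leave out how far populations within LSK cells, or within committed progenitors, differed from each other.

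The Cbl probe was detected on 0 of 13 arrays, with normalized log2 signals between 4.49 and 5.33, so it checks no label. Both Flt3 probes were also detected on 0 of 13 arrays, and no probe named Ly6a was found among those listed. Kit, the stem cell factor receptor used in the sort, was detected on all 13 arrays and differed between A/- and +/+ by 0.13 on the log2 scale (SE 0.08, n = 6 pairs, adjusted p = 0.443). Cd34 was at 6.99 and 6.26 in the +/+ and A/- MEP, a population sorted as CD34-negative, and between 10.01 and 10.21 on the 3 LTHSC arrays, also sorted as CD34-negative. Fcgr3, which encodes the Fc receptor CD16 used to set GMP apart, was at 12.19 and 11.01 in GMP. In MEP, sorted as negative for it, the gene was at 8.60 in +/+ and 4.43 in A/-. Over the 6 pairs Fcgr3 differed by -1.60 (SE 0.41) and Fcgr2b by -0.84 (SE 0.25). Neither passed over all genes (adjusted p = 0.130 and 0.178), and both passed when adjusted over the list alone (0.0125 and 0.0157). Among sex-linked genes, Eif2s3y, which lies on the Y chromosome, was by its brighter probe at 4.64 and not detected in the +/+ LTHSC, and at 9.04 to 10.71 on the other 12 arrays. Xist, the RNA that silences an X chromosome, was detected on all 13 arrays and was 0.70 higher in A/- (SE 0.15, higher in 6 of 6 pairs, adjusted p = 0.0957, or 0.00534 adjusted over the list alone). The Y-linked Kdm5d differed by -0.87 (SE 0.25, adjusted p = 0.167) over the 6 pairs and passed in committed progenitors alone (-1.51, SE 0.20, n = 3 pairs, adjusted p = 0.0375). In LTHSC, Kdm5d was at 6.82 in +/+, 6.97 in A/- and 7.21 in -/-, so it did not share the missing Eif2s3y signal of +/+. Eif2s3y was lower in A/- in each of the 5 pairs outside LTHSC, with differences between -0.66 (MPP) and -1.67 (MEP). The labels give neither the sex of the mice nor whether cells of several mice were pooled, so genotype and sex were not separated here.

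The first comparison asked which transcripts the A/- genotype changed in common across the 6 populations. Tmod4, which caps the slow-growing end of actin filaments, rose by 1.78 on the log2 scale (SE 0.13, n = 6 pairs, adjusted p = 0.00265), with differences between 1.54 and 2.13 in the single pairs. Erdr1 rose by 1.19 (SE 0.11, adjusted p = 0.00479) and H2-T10, a non-classical MHC class I gene, by 1.32 (SE 0.18, adjusted p = 0.0298). Inppl1, the lipid phosphatase SHIP2, rose by 1.24 and Faah, which degrades fatty acid amides, by 1.20. The kinase gene Stk35 rose by 1.26, 1110017D15Rik by 1.17, Clec16a by 1.01, Ocel1 by 0.995, the ceramidase gene Acer2 by 0.95, Ssbp4 by 0.87 and 6820431F20Rik by 0.69. Among the called genes named here the lowest value was that of Psmd8, a subunit of the proteasome cap, at -2.99 (SE 0.43, adjusted p = 0.0320). Ffar2, a receptor for short-chain fatty acids, fell by 2.52 (SE 0.40). Fcnb, a lectin of myeloid cells, fell by 2.43 (SE 0.43, adjusted p = 0.0452). Igll1, part of the surrogate light chain of the pre-B cell receptor, fell by 2.29 (SE 0.33, adjusted p = 0.0320). Itch, itself an E3 ubiquitin ligase gene, fell by 2.14 (SE 0.35, adjusted p = 0.0329). Haus1, of the mitotic spindle, fell by 1.77 (SE 0.19, adjusted p = 0.0115) and the chemokine gene Ccl25 fell by 1.69 (SE 0.19, adjusted p = 0.0143). Wdfy1 fell by 1.45 (SE 0.15, adjusted p = 0.00908). Clec4b1 (-1.75), Mogat2 (-1.55), Arv1 (-1.33) and G0s2, an inhibitor of lipolysis (-1.42), fell too. In the LTHSC pair the differences of Psmd8, Ffar2 and Itch were -0.20, -0.19 and -0.03. For 12 of the named genes 17 further probes were detected, and 16 had the same sign; a second Ccl25 probe was at 1.06.

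In total 76 of 12807 tested features passed in limma, 21 higher and 55 lower in A/-, and 59 of them had a gene symbol (14 higher and 45 lower). The count was 473 without the LTHSC pair, 2 without STHSC, 4 without MPP, 4 without CMP, 7 without GMP and 45 without MEP. With the LTHSC and MEP pairs both left out it was 498, which held 75 of the 76, and with eBayes without its trend it was 11. Across features the LTHSC differences correlated with those of the other 5 pairs at r between -0.136 and -0.0798, and those of the other 5 among themselves at 0.274 to 0.538.

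**Figure D1:**
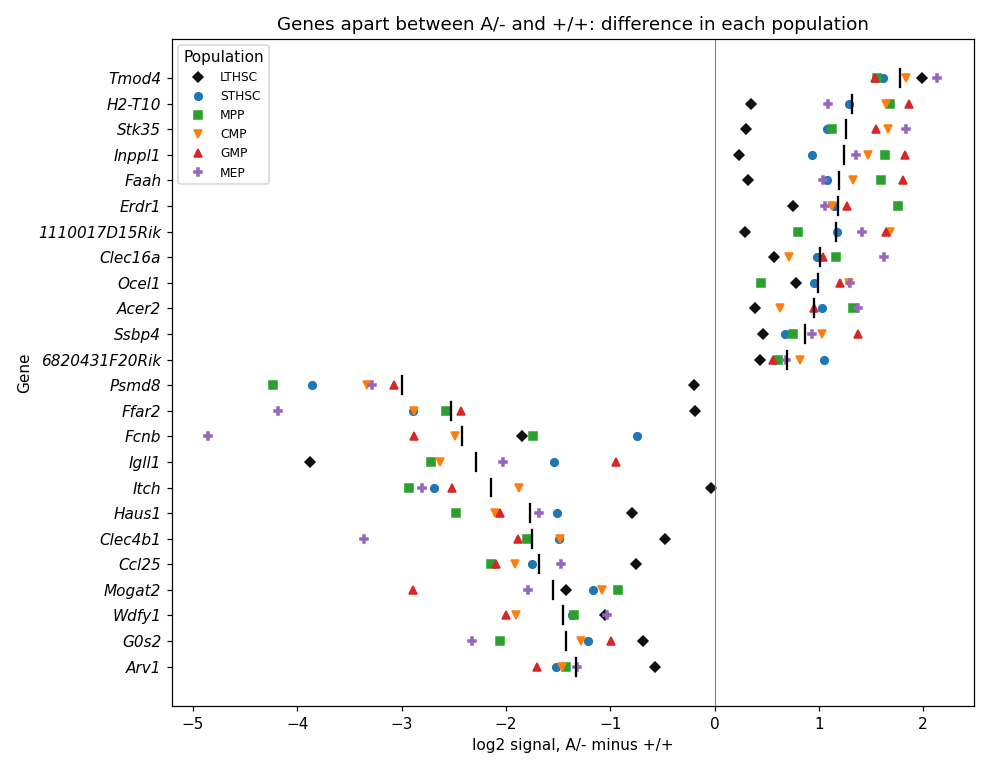
Difference in normalized log2 signal, A/- minus +/+ (horizontal axis), for the 24 named genes of the comparison over 6 populations (vertical axis). Each symbol is 1 population and the black bar is the fitted mean; Tmod4 lies between 1.54 and 2.13 in all 6 pairs, whereas Psmd8 and Itch lie near 0 in LTHSC at -0.20 and -0.03.

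Among 24 fixed gene lists, genes of the granulocyte lineage were lower in A/-. The mature neutrophil list had a median difference of -2.03. Of its 18 measured genes 0 passed over all genes and 15 were lower when adjusted over the list alone. Among them were Camp, the antimicrobial cathelicidin, at -3.10 (SE 0.91, n = 6 pairs), Ltf, the iron-binding lactoferrin of granules, at -2.92 (SE 0.85), and Lcn2, which binds bacterial siderophores, at -2.53 (SE 0.72). The granulocyte-monocyte progenitor list had a median of -1.03. Of its 25 genes Fcnb and Alas1 (-0.53, SE 0.09, adjusted p = 0.0430) fell over all genes, and 16 were lower when adjusted over the list alone, among them Elane, neutrophil elastase (-1.41, SE 0.49), and the transcription factor genes Gfi1 (-1.24, SE 0.42) and Cebpe (-1.47, SE 0.54). Limma's camera with a preset correlation called both lists lower (adjusted p = 6.04e-11 and 6.89e-11). Neither call held with an estimated correlation (adjusted p = 0.378 with an estimated correlation for both). The neutrophil list's median was 0.33 in the LTHSC pair, -1.40 in STHSC, -1.30 in MPP, -1.16 in CMP, -2.92 in GMP and -5.46 in MEP. The progenitor list's median was -0.16 in LTHSC and -2.98 in MEP. In MEP, granule genes were abundant on the +/+ array and lower on the A/- array, with Mpo (myeloperoxidase) at 14.86 and 10.95, Prtn3 at 13.09 and 8.59 and Ctsg at 12.93 and 7.94.

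Markers of other mature blood cells were also lower. Mast cell, basophil and eosinophil genes had a median of -0.71, and 0 of 9 passed over all genes and 6 when adjusted over the list alone, among them the mast cell protease gene Cpa3 (-0.59, SE 0.12) and Mcpt8, a protease gene of basophils (-1.03, SE 0.27). Macrophage and dendritic cell genes had a median of -0.41, with 0 of 17 past over all genes and 6 lower when adjusted over the list alone, among them the adhesion receptor Vcam1 (-1.71, SE 0.33) and Adgre1 (-0.84, SE 0.23), the F4/80 antigen. Camera called both lists lower at adjusted p = 2.86e-05. They had adjusted p = 0.332 and 0.180 with an estimated correlation. In the LTHSC pair the medians of these lists were on the higher side, at 0.29 and 0.12. In the other pairs they lay between -1.32 and -0.17 and between -0.82 and -0.23. The B, T and NK cell list had a median of -0.40, with 0 of 9 genes past over all genes and 3 when adjusted over the list alone, the T cell receptor chains Cd3g (-0.61) and Cd3d (-0.59) and the NK receptor Klrd1 (-0.66). Its camera adjusted p was 0.00660, and adjusted p = 0.222 with an estimated correlation. In the lymphoid priming list (median -0.30, 15 genes, camera adjusted p = 0.0245) Igll1 fell over all genes and Vpreb3 (-1.40) and Vpreb1 (-1.34), the partners of Igll1 in the surrogate light chain, were also lower when adjusted over the list alone. That list had adjusted p = 0.595 with an estimated correlation. Its call was lost without the MEP pair (adjusted p = 0.503) or the LTHSC pair (0.0674), and that of the B, T and NK cell list with 75th percentile scaling (0.0650) or cyclic loess (0.0633).

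The heat shock and p53 lists moved the other way. The heat shock list rose (median 0.42, camera adjusted p = 2.01e-04; adjusted p = 0.230 with an estimated correlation). Of its 9 genes 0 passed over all genes and 5 were higher when adjusted over the list alone, the chaperone genes Hspa1a (0.72, SE 0.18), Hspa4l (0.55, SE 0.13), Hsph1 (0.50, SE 0.11), Hspa8 (0.24, SE 0.07) and Dnajb1 (0.20, SE 0.06). The p53 target list rose (median 0.18, camera adjusted p = 0.00285; adjusted p = 0.190 with an estimated correlation). Of its 13 genes 0 passed over all genes and 4 were higher when adjusted over the list alone, Phlda3 (0.68, SE 0.22), Zmat3 (0.64, SE 0.19), Bbc3, which encodes the death protein PUMA (0.43, SE 0.11), and Ccng1 (0.38, SE 0.10). Cdkn1a, the p21 cell cycle inhibitor of the same list, differed by 0.00 (SE 0.32). The stem cell identity list had a median of 0.24 with 0 of 27 genes past either threshold (camera adjusted p = 0.0245; adjusted p = 0.571 with an estimated correlation). Its median was 1.11 in the GMP pair and -0.40 in the MEP pair, and the call was lost without the GMP pair (adjusted p = 0.335) or the LTHSC pair (0.0840). The interferon list (median -0.22, 0 of 23 genes, adjusted p = 0.00529), the immediate early list (-0.27, 0 of 16, 0.0274) and the respiratory chain list (-0.09, 0 of 68, 0.00660) were called lower by camera. Their values were adjusted p = 0.378, 0.571 and 0.652 with an estimated correlation. The respiratory chain call rests on the MPP pair, with a median of -0.65 there and -0.03 to 0.11 in the other 5, and without it the list was on the higher side and not called (adjusted p = 0.481). The interferon call was lost without MEP (0.0515), and the immediate early call without STHSC, CMP or MEP (0.0972, 0.0825 and 0.0622). In total camera called 12 of 24 lists, 3 higher and 9 lower, and 0 with an estimated correlation (4 had an unadjusted p under 0.05). With the signs of some pairs turned, camera at the preset correlation still called between 2 and 12 lists. By fry, which tests whether a list's genes move on balance one way, 4 lists were called, namely p53 targets (adjusted p = 0.00182), heat shock (0.0236), macrophage and dendritic cell (0.0245) and B, T and NK cell (0.0360).

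The other 12 lists were not called by camera. RAS-ERK feedback genes were at adjusted p = 0.0761 (0.00330, higher, without MEP), with Ccnd1 (cyclin D1, 0.73, SE 0.15) and Etv5 (0.72, SE 0.22) higher when adjusted over the list alone. STAT5 targets were at 0.363, with Socs2 (0.64), Cish (0.53) and Pim2 (0.50) higher and Ccnd2 (-0.50) lower when adjusted over the list alone. In these lists 0 genes passed over all genes. The megakaryocyte-erythroid list was at adjusted p = 0.708 over 33 genes, but it was called higher without LTHSC (0.0221) and lower without GMP (0.0102). Its median was -0.83 in LTHSC and 1.89 in GMP, where 24 of 33 genes were at least 2-fold higher in A/-, with Klf1, an erythroid transcription factor, at 9.38 in +/+ and 11.65 in A/-. Adjusted camera p-values were 0.216 for sort markers, 0.990 for stroma and endothelium, 0.197 for cell cycle, 0.229 for Myc and ribosome biogenesis, 0.229 for FOXO targets, 0.473 for the Cbl family with its receptors and adaptors, 0.205 for HoxA and Meis, 0.826 for sex-linked genes and 0.886 for cytoplasmic ribosomal proteins. In an exact sign-flip test of the 6 pair means, 6 lists reached 0.03125, the smallest two-sided p that 6 pairs allow, which is 0.125 after adjustment over the lists.

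**Figure D2:**
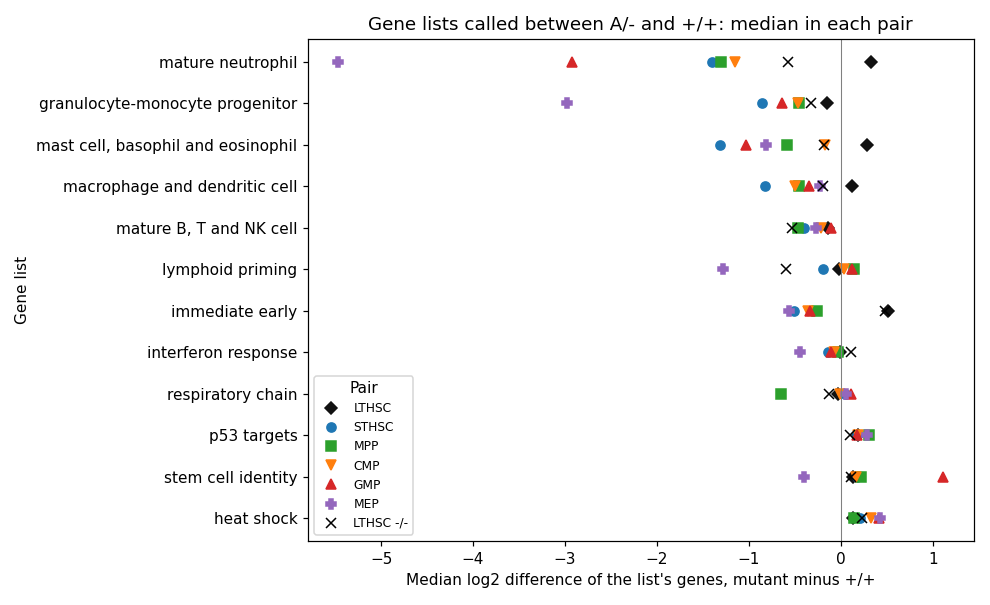
Median difference in normalized log2 signal, mutant minus +/+ (horizontal axis), of the 12 lists called by camera (vertical axis). Each filled symbol is the A/- pair of 1 population and each cross the LTHSC -/- pair; for the mature neutrophil list the A/- medians run from 0.33 in LTHSC to -5.46 in MEP.

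The genotype difference was then taken within the LSK cells and within the committed progenitors. In LSK cells no gene passed. The genes with the smallest p were Tmod4 at 1.72 (SE 0.19, n = 3 pairs, adjusted p = 0.0938), Casp9, the initiator caspase of the mitochondrial death pathway, at -1.24 (SE 0.16, adjusted p = 0.0938), the iron exporter Slc40a1 at -0.99 (SE 0.13, adjusted p = 0.0944) and Erdr1 at 1.22 (SE 0.16, adjusted p = 0.102). The histone genes H2bc9 (-0.94), H4c9 (-0.98) and H2bc11 (-0.95), together with Wdfy1 (-1.25), Rgcc (-0.96) and Igll1 (-2.71), followed at adjusted p = 0.197. Limma called 0 of 12807 features and 898 had an unadjusted p under 0.05. Without the LTHSC pair 81 features passed.

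In committed progenitors the genes of neutrophil granules showed the lowest values. The subunits of calprotectin, S100a8 (-4.53, SE 0.25, n = 3 pairs, adjusted p = 7.26e-04) and S100a9 (-4.63, SE 0.39, adjusted p = 0.0107), fell. The spread behind each SE came from all 6 pairs. S100a8 hardly varied in the LSK pairs, so its SE and p-value may be too small. Camp (-5.45, SE 0.75), Ltf (-5.17, SE 0.65) and Lcn2 (-4.25, SE 0.67) fell as well. The chitinase-like genes Chil3 and Chil4 were at least 17.9-fold and at least 15.3-fold lower. Such a bound sets the mean of the brighter group against the lowest signal that counted as detected, since the probe was detected on none of the dimmer group's arrays. Fcnb (-3.41), Ffar2 (-3.17), Pnp2 (-2.20), Haus1 (-1.95) and Ccl25 (-1.82) also fell. Pawr, a gene that promotes apoptosis, rose by 2.23 (SE 0.27, adjusted p = 0.0375) and Tmod4 by 1.84 (SE 0.19, adjusted p = 0.0234). Zfp30 was at least 2.59-fold and Stk35 at least 1.61-fold higher. Vps39 rose by 1.63, 1110017D15Rik by 1.58, Inppl1 by 1.55, H2-T10 by 1.53, Ocel1 by 1.27, Timmdc1 by 1.25, the p53 target Phlda3 by 1.21 and Gfer by 1.18. In limma 61 features passed, 18 higher and 43 lower, the Y-linked Kdm5d among them. Of the mature neutrophil list 6 of 18 genes fell over all genes and 15 were lower when adjusted over the list alone (median -3.20, camera adjusted p = 6.71e-16; adjusted p = 0.443 with an estimated correlation). In the GMP pair, 1 of the 3 behind this, lists of other cells were higher in A/-, with medians of 1.89 for the megakaryocyte-erythroid list (24 of 33 genes at least 2-fold) and 1.11 for the stem cell identity list (15 of 27). The count was 8 without CMP, 1 without GMP, 9 without MEP and 1 without the eBayes trend. Scaling each array to its 75th percentile moved the median of all features to 0.13 and called 272, 136 higher and 136 lower.

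The difference between these effects was tested itself. S100a8 passed, with the genotype difference 4.53 higher in LSK cells than in committed progenitors (SE 0.36, n = 3 pairs each, adjusted p = 0.0119), being 0.00 in LSK cells and -4.53 in committed progenitors. On the LSK arrays S100a8 lay between 15.10 and 15.42, close to the highest normalized signal of any feature, 15.62. The LTHSC, STHSC and MPP pairs differed by 0.032, -0.137 and 0.117, and the CMP, GMP and MEP pairs by -4.065, -4.012 and -5.506. The fit takes 1 spread from both groups. LSK pairs held close together near the highest signal can therefore make the SE and p-value of S100a8 too small. S100a9 (4.27, SE 0.55, adjusted p = 0.293) and Ltf (4.49, SE 0.92, adjusted p = 0.573) did not pass. Nor did Nod1, a sensor of bacterial peptidoglycan (1.41), Taf10 (-0.81), Lpar6 (0.96), Mrpl34 (-0.85), Eif4a2 (0.63), ND4L (1.34) and Pgls (-0.66), all at adjusted p = 0.573. Limma called 1 feature and 1071 had an unadjusted p under 0.05. The count was 0 without STHSC or without MPP, 3 without LTHSC, 5 without CMP and 2 without MEP, and it was 0 with robust eBayes or without its trend.

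Loss of c-Cbl was compared with the A/- genotype in LTHSC, where each genotype had 1 array, so that there is no replicate check and no p-value. Eif2s3y was at least 27.1-fold higher in -/- and at least 31.1-fold higher in A/- than in +/+, where the +/+ LTHSC array alone of the 13 lacked its signal, so these folds cannot be assigned to c-Cbl. In -/- cells Tmod4 was 2.56 higher on the log2 scale than in +/+, the peptide transporter Slc15a2 2.18, Sox6, a transcription factor gene, 1.96, and Socs2, a feedback inhibitor of cytokine signaling, 1.83. Among the lower genes Tm7sf3 was at least 13.2-fold lower, Igll1 was at -4.33, Sphk1, which makes sphingosine 1-phosphate, at -4.25, Upk3bl at -4.13 and the amino acid transporter Slc38a5 at -4.03. Wfdc2 was at least 11.4-fold and Col5a1 at least 11.8-fold lower. In A/- cells Gdpd3 was at 4.51, Saa3, an acute phase protein, was at least 9.78-fold higher, the cystatin genes Stfa1 and Stfa2 were at 3.37 and 3.27, the platelet chemokine Ppbp was at least 6.94-fold higher and Il1r2, a decoy receptor for interleukin 1, was at 2.55. Slc38a5 was at -4.38, Upk3bl at -4.23, Sphk1 at -4.07, Car1, an erythroid carbonic anhydrase, at -4.01, Igll1 at -3.88 and Klf1 at -3.34. The erythroid surface genes Ermap and Kel were at least 7.70-fold and at least 6.53-fold lower.

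Erythroid genes were bright on the +/+ LTHSC array, with Klf1 at 10.52 there, 8.41 in -/- and 7.18 in A/-, and Car1 at 13.51, 10.32 and 9.50. The megakaryocyte-erythroid list had a median of -0.65 in -/- and -0.83 in A/- against +/+, both at percentile 0 among 10000 random lists matched on mean signal. The immediate early list was at 0.47 and 0.51 (percentile 100 for both), and the mature neutrophil list at -0.57 (percentile 0) in -/- and 0.33 (percentile 100) in A/-. At least 2-fold differences were counted for 435 features in -/- (145 higher and 290 lower) and 476 in A/- (280 higher and 196 lower). Between -/- and A/- themselves there were 482 (131 higher and 351 lower in -/-). The split for -/- was 43 higher and 200 lower with 75th percentile scaling and with cyclic loess 40 of 241 were higher. It was 18 and 110 with the authors' processed values, and 47 and 185 with the array sets normalized apart. The -/- differences correlated with those of the 5 A/- pairs outside LTHSC at r between 0.00616 and 0.277 across features. The same +/+ array served both LTHSC comparisons. Across features the 2 differences correlated at r = 0.464, against 0.502 in simulations with no effect. Their covariance was 0.1001 against 0.0909, and features are not independent replicates. In both comparisons 58 features were higher and 108 lower, and 23 went opposite ways. The simulations gave a mean of 41.3 and 43.8 in both, while lists with no array in common would give 3.17 and 4.44. The simulated spread also holds genotype differences that varied between populations, so the simulated covariance and counts may be too high. With 1 control array the control could not be split, so part or all of the overlap may come from it.

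**Figure D3:**
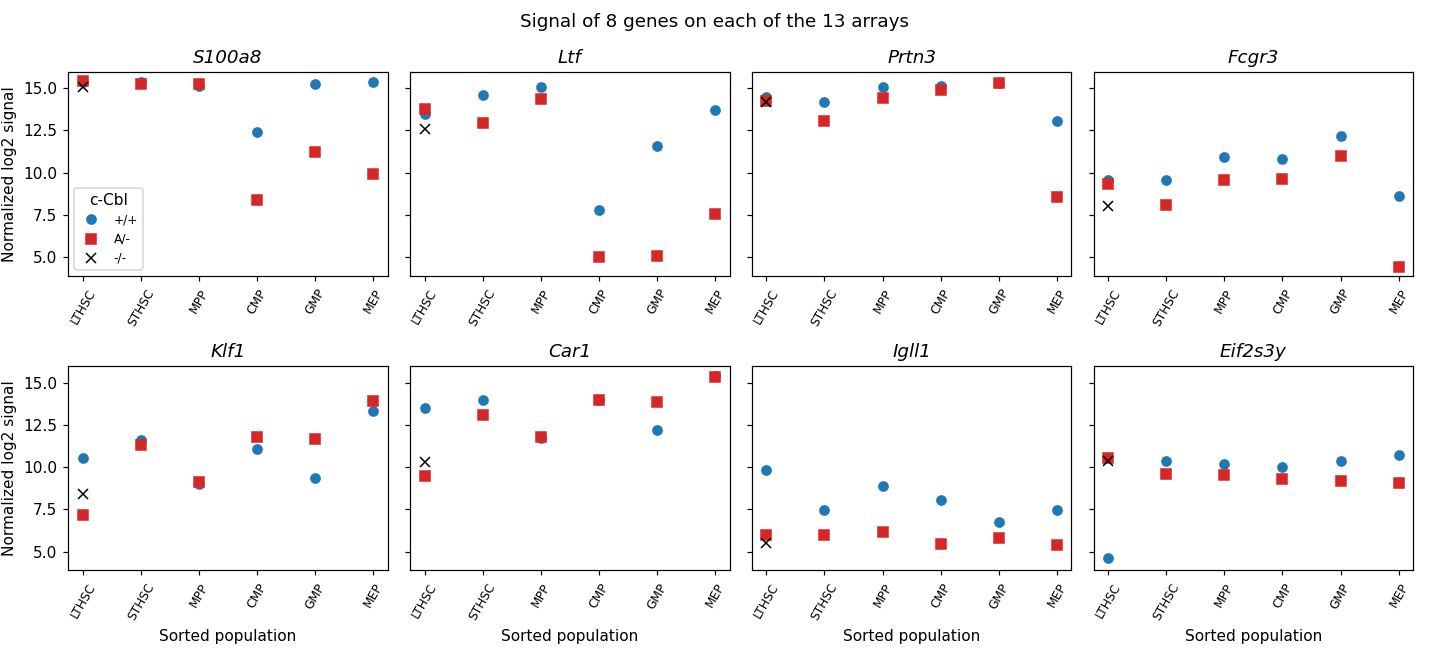
Normalized log2 signal (vertical axis) of 8 genes on each of the 13 arrays, by sorted population (horizontal axis) and c-Cbl genotype (symbol). S100a8 is near 15 in LSK cells of both genotypes, Prtn3 in MEP is at 13.09 in +/+ and 8.59 in A/-, and Eif2s3y is at 4.64 on the +/+ LTHSC array alone.

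Populations were then compared over both genotypes. Between LSK cells and committed progenitors, stem cell identity genes were higher in LSK cells (22 of 27 higher and 2 lower, camera adjusted p = 1.30e-07; adjusted p = 0.158 with an estimated correlation). Nkx2-3, a homeobox gene of stem cells, was 4.80 higher (SE 0.39, n = 6 arrays each, adjusted p = 3.05e-05). The largest positive values included neutrophil genes, with Retnlg at 5.59 (SE 0.58), Ltf at 5.59 (SE 0.85), Ngp at 5.44 (SE 0.93), Camp at 4.94, Fpr2 at 4.87, Lcn2 at 4.55 and Chil4 at 4.29. Part of these values came from the lower levels in A/- committed progenitors, as Ltf differed by 3.34 among +/+ and 7.83 among A/- arrays, and Camp by 2.59 and 7.28. Retnlg still differed by 4.68 among +/+ arrays. Whether LSK cells themselves or mature neutrophils carried over in their sorts held this RNA was not tested, so these values do not show expression in stem cells. Of the mature neutrophil list 17 of 18 were higher (camera adjusted p = 2.20e-06; adjusted p = 0.310 with an estimated correlation). Of the megakaryocyte-erythroid list 19 of 33 were lower in LSK cells and 6 higher (camera adjusted p = 0.0142; adjusted p = 0.656 with an estimated correlation). Among the lower genes were Ermap at -2.68 (SE 0.56, adjusted p = 0.00435), the membrane skeleton gene Add2 at -2.57 and Kel at -2.41. Col5a1 (-2.55), Sphk1 (-2.51), Spon2 (-2.49), Tlcd4 (-2.43) and Atp1b2 (-2.41) were lower too. These differences were also smaller among +/+ than among A/- arrays, for Ermap -1.35 against -4.00. Of the Myc and ribosome biogenesis list 20 of 26 genes were lower (camera adjusted p = 1.67e-06; adjusted p = 0.158 with an estimated correlation). In limma 5877 features passed, 3026 higher and 2851 lower in LSK cells, and 3176 without MEP. Other splits of the 6 populations into 3 and 3 called between 2027 and 4641. The split was 2067 higher and 5620 lower with 75th percentile scaling, which moved the median of all features to -0.27, and 3619 and 2090 with cyclic loess.

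Between STHSC and LTHSC, F2rl2, a thrombin receptor gene, was at least 19.4-fold higher in STHSC, Mrvi1 was 3.95 higher (SE 0.52, n = 2 arrays each, adjusted p = 0.00573), Pde10a at least 9.50-fold, the heat shock gene Hspa1a at least 8.29-fold and Lim2 at least 7.28-fold. The platelet glycoprotein gene Gp1bb was 3.41 higher, Pdzph1 3.15 and Mfsd2b 3.07. Of 29 cell cycle genes 10 were higher in STHSC and 0 lower (camera adjusted p = 3.32e-08; adjusted p = 0.293 with an estimated correlation). BC018473 was at least 13.2-fold lower in STHSC, Sult1a1 was at -4.55 (SE 0.51, adjusted p = 0.00486), and Socs3, a feedback inhibitor of cytokine signaling, at -3.37. Trib3 was at least 9.63-fold, Unc45b at least 8.58-fold, Cpne8 at least 6.18-fold and Bmp4 at least 3.02-fold lower, and Wfdc2 was at -3.20. In limma 1429 features passed, 723 higher and 706 lower. The LTHSC arrays form a set of their own in signal level, so population and array set cannot be told apart here. The count was 5 without the STHSC A/- array, 220 without STHSC +/+ and 301 without LTHSC A/-. With 75th percentile scaling it was 4589, 3406 higher and 1183 lower, with a median of all features at 0.24.

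MPP were then set against STHSC. Dntt, the DNA polymerase of antigen receptor rearrangement, was 4.96 higher in MPP (SE 0.66, n = 2 arrays each, adjusted p = 0.00503), Satb1, a chromatin organizer of lymphoid cells, 3.17 (SE 0.35) and Notch1 2.81 (SE 0.51). Sstr2 was 4.08 higher, Arpp21 at least 9.98-fold, Tspan2 2.92, Sgsm1 at least 4.23-fold and Tmem108 at least 3.69-fold. Vwf, von Willebrand factor, was at -5.24 (SE 0.56, adjusted p = 0.00281) and Pf4, platelet factor 4, at -4.88 (SE 0.58), while Gp1bb was at least 32.2-fold lower in MPP. Cavin2 was at -6.04, Treml1 at -5.06 and Mfsd2b at -4.36, and F2rl2 and Ehd3 were at least 18.3-fold and at least 13.6-fold lower. The lymphoid priming list was higher in MPP (5 of 15 higher and 1 lower, 9 higher when adjusted over the list alone, camera adjusted p = 4.40e-05; adjusted p = 0.620 with an estimated correlation) and the stem cell identity list lower (9 of 27 lower and 0 higher, 5.52e-06; adjusted p = 0.595 with an estimated correlation). In limma 690 features passed, 349 higher and 341 lower. The count was 1728 without the MPP +/+ array, 40 without MPP A/-, 148 without STHSC +/+ and 17 without STHSC A/-. With 75th percentile scaling the median of all features moved to -0.10.

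Between GMP and CMP no gene passed. The eosinophil granule gene Prg3 (2.54, SE 0.41, n = 2 arrays each) had a positive value in GMP, and Prom1 and G0s2 were at least 3.04-fold and at least 3.32-fold higher there. The chemokine gene Ccl5 (-2.04, SE 0.28), Ctsw, a protease of cytotoxic lymphocytes (-1.63), the T cell receptor segment Trbv13-2 (-2.58), Epb41l3 (-1.93) and Tespa1 (-1.22) had negative ones, and Depp1 and Tox were at least 2.34-fold and at least 2.08-fold lower. All 10 were at adjusted p = 0.140. Limma called 0 features and 845 had an unadjusted p under 0.05. It called 4 without the GMP +/+ array and 1 without GMP A/-. With 75th percentile scaling 18 passed, 9 higher and 9 lower.

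Between MEP and CMP the erythroid genes were higher in MEP. The globin genes Hba-a1, Hbb-bt and Hbb-bs were 5.96 (SE 0.89, n = 2 arrays each, adjusted p = 8.25e-04), 5.01 and 4.90 higher. Slc4a1, the anion exchanger of red cells, was at least 23.1-fold, Trim10 at least 30.0-fold and the membrane skeleton gene Dmtn at least 15.7-fold higher, while Pdia2 was 4.69 and Plpp1 4.54 higher. Irf8, a transcription factor gene of monocytes and dendritic cells, was at least 59.2-fold lower in MEP, Ly86 at least 43.9-fold, Fgd2 at least 18.1-fold and Parp8 at least 13.5-fold. F13a1, a coagulation factor gene of monocytes, was at -6.81 (SE 0.57), Serpinf1 at -5.95 (SE 0.12, adjusted p = 1.64e-08), Emb at -5.54 and Mpeg1 at -5.43. Of the megakaryocyte-erythroid list 24 of 33 were higher and 1 lower (camera adjusted p = 1.72e-07; adjusted p = 0.350 with an estimated correlation), and of the granulocyte-monocyte list 22 of 25 were lower (2.46e-10; adjusted p = 0.319 with an estimated correlation). In limma 4170 features passed, 1850 higher and 2320 lower. The count was 2617 without the MEP A/- array, 2464 without CMP +/+ and 2452 without CMP A/-. With 75th percentile scaling the split was 3493 higher and 1888 lower, with a median of all features at 0.31.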

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

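The tests of mature neutrophils alone (in MEP and in the other pairs), of the GMP share below the highest signal, of the position of the A/- LTHSC array and of exchanged LTHSC labels were chosen only after the result was seen. Of 32 groups of 6 values examined for a value far from the rest, 8 had one, and chance gives about 1 in 20.

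Outside LTHSC genes of neutrophils and their progenitors were lower in A/-, though 0 of 18 neutrophil genes passed over all genes and that list's median was 0.33 in LTHSC, and the MEP pair stood apart from the other 5 in the granulocyte-monocyte list (median -2.98, next -0.86, gap over range 0.752). Mature neutrophils alone in the +/+ MEP sample are argued against, because Mpo, Elane, Prtn3 and Ctsg, granule genes made in progenitors, had a median of -4.59 in that pair. Cells of the GMP gate alone are argued against too, since the excess in +/+ MEP would have to be 1 share of the GMP signal and its log2 had an SD of 2.71 over 38 of 43 genes (5 were not detected on both +/+ arrays or not higher in +/+ MEP), and 2.89 over the 31 more than 1 below the highest signal in GMP. In STHSC, MPP, CMP and GMP the same granule genes had a median of -0.407 beside -1.54 for the neutrophil list; they lay a median of 0.566 below the highest signal on the arrays, so mature neutrophils and a change within the progenitors cannot be told apart there. In the GMP pair megakaryocyte-erythroid (1.89) and stem cell identity genes (1.11) were higher in A/-, so a mixture of stages carried over the lineage and CD16/32 gates, and an effect of the genotype on granulocyte genes, both stay open, and may differ between pairs.

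The LTHSC pair did not follow the other 5 pairs. Across genes its differences correlated with theirs at r between -0.136 and -0.0798, while the other 5 correlated among themselves at 0.274 to 0.538. Joint normalization is argued against, since the mean r was -0.105 with the array sets normalized apart, whereas the array set itself was not tested, all LTHSC arrays being in the dim one. At the 7 features at least 4-fold apart one way in all other 5 pairs, Psmd8, Ffar2, Cptp, Dmkn, Tedc2 and 2 unnamed ones, the A/- LTHSC array lay at a median position of 0.0898, where 0 is the +/+ level and 1 the A/- level, and the -/- array at 1.02, but the +/+ LTHSC array itself lay at 0.479, so an A/- array of another genotype or background and one of the same cannot be told apart by this. With the array labelled -/- in the place of A/-, as exchanged labels would have it, the mean r was 0.161. That is below the 0.274 to 0.538 among the other 5 pairs. Set against the array labelled A/- it was 0.252, but this also puts that array in the place of +/+. Exchanged labels may thus explain part of it but were not shown. The missing Eif2s3y signal of the +/+ LTHSC sample may play a part too, though Kdm5d, also Y-linked, differed by only 0.15 between A/- and +/+ LTHSC. A biological difference of these stem cells may do so as well and was not tested. All values above keep the labels as given.

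Of the genes called over the 6 pairs, 8 had another called gene among their 10 tested neighbours on either side, against a median of 6 and a 95th percentile of 12 in random sets. This argues against linked alleles around a few loci as the whole source. It cannot see a linked gene that has no called neighbour, and the region around Cbl was not examined apart, so linkage stays open for single genes. Also, 4 of the 8 lay on chromosome 8, so a linked segment there stays open for some of them. In the normalized values, genes of like brightness carried a median share of -0.00776 of the called genes' differences. Normalization by quantiles had already brought the arrays to equal distributions, so a small share was likely in any case. The share therefore cannot tell whether the dimmer A/- arrays affected the called genes, and this stays open. Chance is not excluded for the count, since 2 of the 32 ways of turning the signs of pairs called at least 76 features. The highest other was 158, with the LTHSC pair turned, which points to the structure of the samples described for that pair. Chance stays open for the 12 lists too, as 2 of 32 splits called as many (highest other 12). The other splits called between 2 and 12 lists, so camera with its preset correlation called lists under every turning of the signs. Its small adjusted p-values therefore do not by themselves set the real split apart.

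For the remaining counts the splits are too few for a share under 0.05. In LSK cells 0 features were called and at most 14 in another split, with 4 of 4 splits as high. In committed progenitors the real split called 61 and the highest other 0 (1 of 4). The difference of the effects gave 1 and 0 (1 of 10), and LSK cells against committed progenitors 5877 and 4641 (1 of 10).

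The genotype difference of S100a8 was 4.53 higher in LSK cells than in committed progenitors by the test of that difference, but its LSK signals of 15.10 to 15.42 lay close to the highest signal on the arrays, 15.62, where a difference would be hard to see. Signals that close to the highest one also vary little between pairs, which can make the SE of that test too small. The sort marker list had its lowest pair median in MEP (-1.45, next -0.41, gap over range 0.722). The lymphoid priming list was also lowest in MEP (-1.29, next -0.19, 0.763), as was the interferon list (-0.44, next -0.14, 0.700). The immediate early list was highest in LTHSC (0.51, next -0.26, 0.715). The respiratory chain list was lowest in MPP (-0.65, next -0.03, 0.815). Eif2s3y was at 4.64 in the +/+ LTHSC against 9.98 to 10.71 in the other +/+ samples (0.879), and at 10.57 in the A/- LTHSC against 9.04 to 9.59 in the other A/- samples (0.642).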

How the results depend on the processing

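The array sets normalized apart, the LTHSC and MEP pairs left out together, and single arrays left out of the steps between populations were chosen after seeing the data. The labels give no replicate numbers, and population served as the block that pairs the arrays. Slide as a block was not run, as the files used here give none. The authors' processed values and the array sets normalized apart gave no value for LSK cells against committed progenitors or STHSC against LTHSC, because the sets were normalized separately. At most 38.0% of probes were detected on any array. The named genes had 2220 values under alternatives. Of these 1864 kept direction and side of the threshold, 321 no longer passed, 35 newly passed and 0 turned direction; Tmod4 over 6 populations passed in all 20 settings. Of 178 counts 112 stayed within 1.5 times, and the cause of the others was not tested except where fewer samples were used.

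Over 6 populations 76 features became 11 without the eBayes trend, 412 with array weights, 4 without the population block, 120 with the -/- array as mutant, 498 without the LTHSC and MEP pairs, and 2 to 473 leaving out 1 pair. In LSK cells 0 became 5 without a filter, 1 with all probes, 4 with robust eBayes, 6 with array weights, and 0 to 81 leaving out 1 pair. In committed progenitors 61 became 95 without background correction, 272 with 75th percentile scaling, 97 with the authors' values, 98 without a filter, 105 with all probes, 1 without trend, 557 with array weights, 157 with the 3 pairs fitted alone, and 1 to 9 leaving out 1 pair. The difference of effects went from 1 to 2 without a filter, 0 without trend, 0 with robust eBayes, and 0 to 5 leaving out 1 pair. LSK cells against committed progenitors ran from 3176 to 6092 leaving out 1 pair. STHSC against LTHSC went from 1429 to 4589 with 75th percentile scaling and 5 to 1305 leaving out 1 array. MPP against STHSC went from 690 to 423 with array weights and 17 to 1728 leaving out 1 array. GMP against CMP went from 0 to 18 with 75th percentile scaling, 29 with array weights, and 0 to 4 leaving out 1 array. MEP against CMP ran from 2452 to 3221 leaving out 1 array. A population left with 1 array is assumed to vary like the others. The 12 lists called over 6 populations became 0 with an estimated correlation and were 11 to 13 otherwise, though not always the same lists. Calls were lost for stem cell identity (without LTHSC or GMP), lymphoid priming (without LTHSC or MEP, without background correction, with the authors' values, with detection on 6 arrays), B, T and NK cell (75th percentile scaling, cyclic loess), immediate early (without STHSC, CMP or MEP), interferon (without MEP) and respiratory chain (without MPP). Lists newly called higher were megakaryocyte-erythroid and Myc without LTHSC, RAS-ERK feedback without MEP, without a filter and with detection on 6 arrays, FOXO targets and HoxA without MEP, and cytoplasmic ribosomal proteins with 75th percentile scaling or cyclic loess. Newly called lower were megakaryocyte-erythroid without GMP and cell cycle without MPP.

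The LTHSC counts without test, 435 for -/- and 476 for A/-, were 143 and 160 without background correction, 238 and 273 with offset 50, 243 and 248 with 75th percentile scaling, 241 and 247 with cyclic loess, 128 and 136 with the authors' values, and 232 and 253 with the array sets normalized apart. With detection on both arrays -/- had 281.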

Other observations

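The comparison of the -/- and A/- LTHSC arrays with each other and the count by chromosome were chosen after the result was seen. In LSK cells camera called the megakaryocyte-erythroid list lower in A/- (median -0.36, adjusted p = 2.37e-05; adjusted p = 0.558 with an estimated correlation), and in committed progenitors higher (0.67, 1.27e-04; adjusted p = 0.542 with an estimated correlation). It also called the difference (median -1.17, adjusted p = 4.47e-11; adjusted p = 0.590 with an estimated correlation). In all 3 cases 0 of 33 genes passed, over all genes or over the list alone. The pair medians farthest from 0 were those of LTHSC (-0.83) and GMP (1.89), while the STHSC, MPP, CMP and MEP medians were -0.09, 0.03, 0.32 and 0.04. In CMP 29 of 33 genes were above 0 (percentile 100 among the matched random lists). How far these calls rest on single pairs was not tested. For RAS-ERK feedback genes in LSK cells the median was 0.40 (camera adjusted p = 0.00287; adjusted p = 0.553 with an estimated correlation), but 0 of 11 genes passed over all genes and 1 when adjusted over the list alone, with 7 above 0 and 4 below. The medians were 0.59 in LTHSC, 0.17 in STHSC and 0.78 in MPP, and -0.10 for the -/- LTHSC array against +/+. The LTHSC and MPP pairs also stood apart in other lists (immediate early 0.51, respiratory chain -0.65). The difference from committed progenitors was not called (adjusted p = 0.149). For STAT5 targets in LSK cells the median was 0.25 (camera adjusted p = 0.0272; adjusted p = 0.558 with an estimated correlation), with 0 of 13 genes past over all genes or over the list alone, and the difference from committed progenitors was not called (0.0613).

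Between the LTHSC arrays labelled -/- and A/-, which share no control, Slc15a2 was 2.49 higher in -/- and Rab6b 2.37. BC018473 was at least 36.5-fold lower in -/-, Saa3 at least 10.8-fold, and the protease inhibitor Slpi, Trim30a, Naip5 and Hbb-bs were at -4.13, -3.77, -3.51 and -3.49. There is no replicate of either. Of the 59 called genes with a position, 9 lay on chromosome 8, which held 536 of the 10020 tested genes with one (Fisher's exact test, p = 0.00384, adjusted p = 0.0677 over the chromosomes). They include 4 of the 8 called genes with a called neighbour, Trappc5, Ccl25, 6820431F20Rik and Smim19.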
